A study of Mus musculus with 2 samples.

How the data were processed

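RNA from mouse liver mesothelial cells was measured on 2 Affymetrix whole-genome expression arrays, 1 for each stage. Per the labels' protocols, livers of C57BL/6 mice were digested with collagenase and mesothelial cells were isolated on a cell sorter with antibodies to PCLP1 or to Mesothelin. Total RNA was purified with a column kit, and 10 ng of it went through 2 cycles of cDNA and cRNA synthesis to give the biotin-labelled cRNA that was hybridised. This kind of linear amplification starts from the 3' end of the transcript, so that signals of probes far from that end fall with partial degradation or short products.

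The authors deposited, per the file headers, a raw signal and a detection call for each of 45101 probe sets on each array. The raw signal is an intensity on a linear scale, as deposited by the authors, and Affymetrix Expression Console is named in the submitters' processing notes. The algorithm that summarised probes into probe sets, its version and its settings are not given in the sources used here. The detection call, of other kind than a measurement, is present, marginal or absent per the file headers. The authors also deposited a ratio of the adult array to the E12.5 array. Tested on the values, this ratio is the raw adult signal divided by 0.680 times the raw E12.5 signal, where the constant is the ratio of the median raw signals of the arrays over all probe sets. It stood at a floor of 0.01 for 78 probe sets. The series' value table held the raw signals again, rounded, with a linear scale, no centring and no common scaling.

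The raw signals were not on a common scale: their medians were 44.0 at E12.5 and 29.9 in adult, and their 2% trimmed means 253 and 139. The plan, fixed before the data were examined, was to keep values that were already normalized as deposited and otherwise to quantile normalize them. The authors' ratio was already normalized and the raw signals were not, so the plan could be read either way. The authors' median scaling was taken as the main setting, a decision made after the column medians had been looked at, and quantile normalization as an alternative. Of 2-fold differences, 67.1% lay towards E12.5 under the former and 53.4% under the latter. Adult signals were divided by that constant, a shift of 0.56 on the log2 scale, and all adult signals given are scaled in this way unless called raw. Differences are log2 signal at E12.5 minus log2 signal in adult, with no pseudocount and no floor.

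A probe set was taken as detected on an array where its call was present. The 64 control probe sets were set aside. Genes were named from the platform annotation, and symbols were updated through Entrez gene numbers with a RefSeq table of the GRCm38.p6 mouse assembly. Of the other 45037 probe sets, 34945 had 1 gene symbol (34741 of these found in the RefSeq table by number), 932 had several and 9160 had none. Probe sets with several symbols were named for no gene. The 34945 probe sets covered 18193 genes. A gene was represented by its probe set with the highest mean log2 signal among those detected on at least 1 array. Coordinates are not given, because the sources used here do not tie the array annotation to a genome build.

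With 1 array per group there are no replicates, so that no test across samples, p-value or SD between samples was computed. Genes were counted at 2-fold and 4-fold among those detected on both arrays. For a gene called present on 1 array and absent on the other, the fold is a lower bound: the bright signal over the higher of the dim probe set's own signal and the lowest signal of any detected probe set on the dim array (4.57 at E12.5 and 5.84 in adult). As a yardstick, the SD of log2 differences between probe sets of the same gene was pooled over 4279 genes and 11071 probe sets detected on both arrays. It measures how far probe sets on the same 2 arrays disagree and not the error between arrays.

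Before the data were examined, 25 gene lists with 577 entries (560 distinct genes) were fixed from general knowledge. Of the listed symbols, 2 had no match in the RefSeq table. For each list the members at least 2-fold higher on either array were counted, members detected on 1 array alone by their bound. The median log2 difference was taken over members detected on at least 1 array. Its percentile was taken among 10000 random lists of the same size, drawn with replacement from the detected genes within 20 bins of mean log2 signal. These percentiles describe the arrays and are not tests of the conditions.

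The rule for named genes, also fixed in advance, took the genes of the sorting antigens first. It then took the 15 genes with the largest difference in each direction among genes detected on both arrays, and the 10 with the largest lower bound in each direction among genes detected on 1 array alone, clone-like symbols skipped. From each list it took up to 4 detected members with the largest absolute difference, and all members of lists with 5 or fewer. Genes named outside this rule were chosen after their values were seen. In the Results part these are Wt1, Upk3b, Krt18, Tbx18, Tcf21, Tyms, Cdkn1b, Sgce, Meg3, Gata4, Hand2, Col1a1, Dcn, Bgn, Ogn, Bmp4, Cfi, H2-K1, B2m, Dnajb1, Fos, Egr1, Ldha, Alb, Ttr, Cyp3a11, Mpo, S100a8, S100a9, Csf1r, Cd5l, Ramp2, Stab2, Pdgfra, Acta2 and Krt19. The globin probe sets and all gene families were likewise added after the data were examined. Families came from 24 patterns of gene symbols, of which 12 were kept, and 5 of the kept patterns were then narrowed to the family proper. This removed 2 Hox and 1 Sox antisense transcripts, Irgq, Cyp51 and the ephrins, and added Igtp. Second marker lists were also written after the data were examined, for the carry-over tests of the closing part. The genes named from them were picked after their values were seen.

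Each result was recomputed under 9 other settings fixed in advance, changing 1 choice at a time. For scaling, the median difference of genes detected on both arrays was set to 0, or the arrays were quantile normalized. For low signals, both arrays were raised to a floor at the 5th percentile of detected probe sets, or a pseudocount of 16 was added. For probe sets, all detected probe sets of a gene were averaged, or those with identifiers ending in _x_at or _s_at were left out. For detection, no filter was used, or a signal above the array's median replaced the call. For the source of values, the unscaled series table was used. List medians were also taken over members detected on both arrays only, and with members detected on 1 array at their bound.

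The counting and list steps were tested on simulated data built on 10154 genes. Of genes given a true log2 difference of 1.5 towards E12.5, 72.0% were called 2-fold, of those at -1.5, 80.0%, and at 2.0 and at -2.0, 96.0% each. Among unchanged genes 10.5% were called 2-fold, among 100 unchanged lists 7.00% fell outside the central 95% of random lists, and 100% of lists shifted by 1 were found. These shares follow from the noise that was set. The measured differences had an SD of 1.364 and a median of 0.375, so that the shares are no rates of error or recovery for these arrays. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision of every value.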

Results

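Liver mesothelial cells, the epithelial-like sheet that covers the surface of the organ, were profiled at embryonic day 12.5 (E12.5) and in 8-week-old adult mice. The series was designed to obtain expression profiles of these cells at both stages. The E12.5 cells had been sorted for PCLP1, the product of Podxl and a sialomucin of podocytes and mesothelium, and the adult cells for Mesothelin, a cell surface glycoprotein of mesothelium. Each group was represented by 1 array, so that no difference given here could be set against a spread between replicates, and stage, sorting antibody and array cannot be told apart. Of 45037 probe sets other than controls, 51.9% were called present on the E12.5 array and 52.2% on the adult array. In all, 12801 genes were detected on at least 1 array and 10154 on both.

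The genes of the sorting antigens were examined first, as a check of the labels. Podxl (Entrez gene 27205) had a signal of 6069 at E12.5 and 1807 in adult, 3.36-fold higher at E12.5. Msln (Entrez gene 56047) had a signal of 48.5 at E12.5 and 11835 in adult, 244-fold higher in adult. Both genes were higher on the array whose label names their product. Since the cells were picked on these antigens, the values are no finding about stage.

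The E12.5 array carried higher signals of most cell cycle, imprinted and hepatoblast genes of the fixed lists, and the adult array higher signals of most complement, antigen presentation and macrophage genes. Among genes detected on both arrays, the largest difference towards E12.5 was that of Dlk1 (Entrez gene 13386), a membrane-bound and shed Notch-family ligand, with signals of 8623 and 67.3 (128-fold). Asb4 (80.9-fold), the heparin-binding growth factor Ptn (80.0-fold), the CDK inhibitor Cdkn1c (59.5-fold), the sister chromatid cohesion factor Dscc1 (43.2-fold), the microfibril protein Fbn2 (42.9-fold) and Mdk, a relative of Ptn (41.5-fold), followed. Towards adult, Msln was followed by the complement protease C1s1 (Entrez gene 50908; 38.7 at E12.5 and 7540 in adult, 195-fold), Fgf1 (143-fold), Igfbp6 (133-fold), the protease inhibitor Slpi (127-fold), the chemoattractant Rarres2 (114-fold), Mndal (109-fold) and Igfbp7 (105-fold). Further down at E12.5 stood Rrm2, Rad51ap1 and Hells (41.2, 40.6 and 39.7-fold), genes of DNA replication and repair. Colec10 (39.2-fold), Bex2 (37.5-fold), St8sia1 (36.8-fold), Hmgb3 (36.3-fold) and Bub1 (35.1-fold) came next. In adult these places were held by Oasl2, Car3, Ahnak2, Clec4g, Anxa8, Mfap5 and Tm4sf1 (between 76.4 and 72.1-fold). These folds are those of 1 probe set per gene, and with all detected probe sets averaged many log2 differences changed. At E12.5 those of Dlk1 (5.70), Ptn (4.02 in place of 6.32) and Dscc1 (3.57 in place of 5.43, and 4.51 with a floor on low signals) were smaller. So were those of Rad51ap1 (4.12 in place of 5.34), Hells (4.07), St8sia1 (4.06) and Bub1 (3.99). In adult those of Car3 (-4.18 in place of -6.25), Fgf1 (-5.81 in place of -7.16), Rarres2 (-5.76 in place of -6.83), Igfbp7 (-5.87) and Mfap5 (-5.54) were smaller. Those of Rrm2 (6.03), Mndal (-8.36), Anxa8 (-6.99) and Tm4sf1 (-6.37) were larger, and Asb4 (6.27) and Fbn2 (5.36) changed little.

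Of genes with a present call on 1 array and an absent call on the other, 1257 were detected at E12.5 alone and 1159 in adult alone. The largest bounds at E12.5 belonged to the fetal plasma protein Afp (Entrez gene 11576), at least 562-fold with a signal of 9666, Nt5dc2 and the slow skeletal troponin Tnni1 (at least 365-fold each), the basement membrane protein Frem2 (179-fold), Igfbp1 (120.0-fold) and Mfap4 (112-fold), each a lower bound. In adult they belonged to Clec4f (Entrez gene 51811), a lectin of resident liver macrophages, at least 788-fold with a signal of 4054, the intermediate filament gene Prph (at least 736-fold), xanthine dehydrogenase Xdh (at least 508-fold), the complement protease C1ra (at least 434-fold), Spock2 (at least 369-fold) and Pcnx2 (at least 328-fold).

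Across the 10154 genes detected on both arrays, 2748 were at least 2-fold higher at E12.5 and 1345 in adult, and 6061 lay within 2-fold. At 4-fold the counts were 722 and 549. The share of 2-fold differences towards E12.5, 67.1% in the authors' scaling, was 45.6% with the median of detected genes set to 0, 53.4% after quantile normalization and 85.4% without scaling, so that the size of this imbalance depends on the scaling and its direction on whether the detected genes are centred. The median difference of detected genes was 0.38 on the log2 scale, and these scalings moved it by -0.38, -0.26 and 0.56. The signals of the arrays correlated across genes with a Pearson r of 0.733 (log2 signals) and a Spearman rho of 0.722, where genes are not independent replicates. Probe sets of the same gene differed with an SD of 0.62 on the log2 scale, and among 2086 genes at least 2-fold apart with several detected probe sets, 329 had probe sets that differed in direction.

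**Figure D1:**
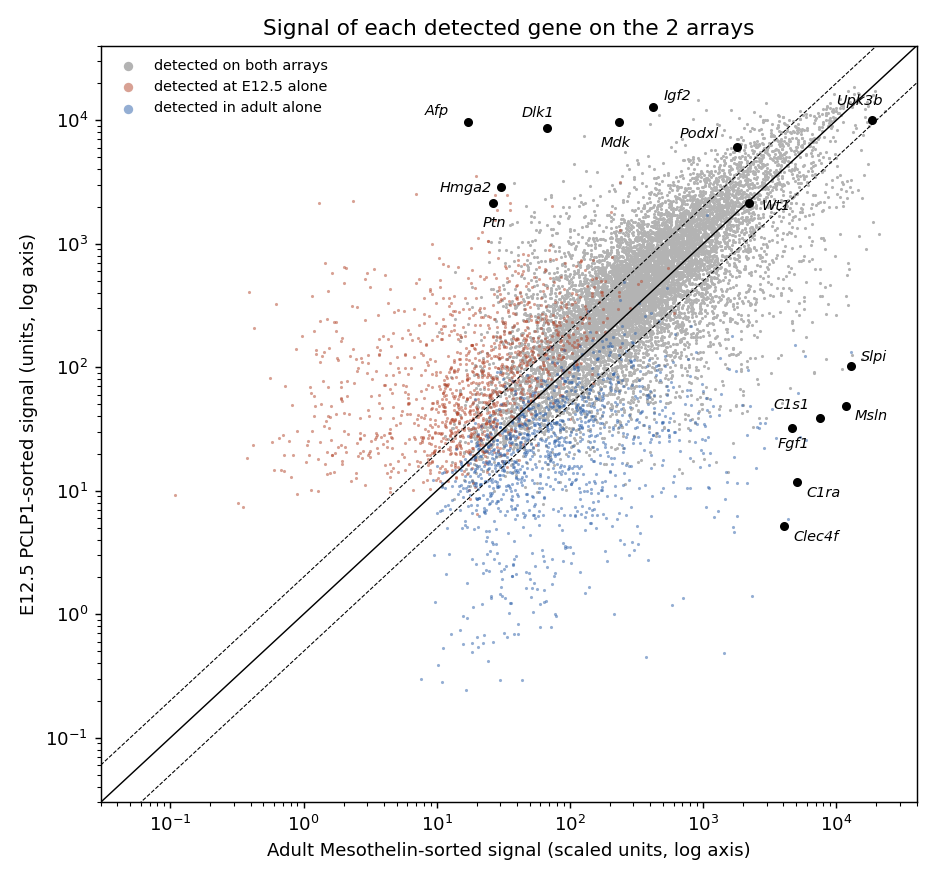
Signal of each detected gene on the adult array (horizontal, scaled units, log axis) and the E12.5 array (vertical, units, log axis), 1 point per gene; the solid line marks equal signals and the dashed lines 2-fold differences. Genes detected at E12.5 alone are red and in adult alone blue; Dlk1 lies 128-fold above the line of equal signals and C1s1 195-fold below it, while Wt1 lies on it.

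Mesothelial marker genes were mostly as high or higher on the adult array. Of 27 detected members of the list, 14 were at least 2-fold higher in adult, 3 at E12.5 and 10 neither, with a median log2 difference of -1.84, with or without the sorting antigens. The counts include both sorting antigens. The 3 at E12.5 were Podxl, Tbx18 and Tcf21, the last with probe sets that differed in direction. After Msln, the largest differences were those of Slpi (102 at E12.5 and 12994 in adult), Nkain4 (at least 47.8-fold) and Gas6, a ligand of TAM receptors (380 and 11889, 31.3-fold). Members with strong signals on both arrays, picked after their values were seen, included the transcription factor Wt1 (2152 and 2228), the keratin Krt18 (2486 and 2667) and the uroplakin Upk3b (10114 and 18571), all within 2-fold. The list median was below those of the 10000 random lists (percentile 0). Markers of hepatoblasts and erythroid cells went the other way (medians 2.02 and 4.51), and whether the share of other cells in each sort bears on the mesothelial median was not tested. Genes of epithelial junctions went both ways, with 5 of 21 higher at E12.5, 6 higher in adult and 10 neither, and a median of -0.27 (mean -0.01, percentile 3.90) that turned to 0.29 without scaling, and also with no detection filter and without probe sets that may match several genes. The desmosomal genes Dsc2 (at least 96.1-fold) and Dsp (9.43-fold) were higher at E12.5, and the claudins Cldn15 (15.7-fold) and Cldn10 (at least 18.1-fold) in adult.

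Cell cycle genes were higher at E12.5 almost without exception. Of 35 detected members 34 were at least 2-fold higher at E12.5, none in adult, and the median difference was 3.78 (percentile 100). The ribonucleotide reductase subunit Rrm2 had signals of 4398 and 107 (41.2-fold), the spindle checkpoint kinase Bub1 was 35.1-fold and survivin (Birc5) at least 27.5-fold higher, and cyclin E1 (Ccne1) had 2284 and 65.3. Tyms, the member within 2-fold, had low signals on both arrays (36.2 and 26.3), and its probe sets differed in direction. Of 13 detected members of the list of CDK inhibitors and quiescence genes 7 were at least 2-fold higher in adult, none at E12.5 and 6 neither, with a median of -1.18 (percentile 0.02), but the CDK inhibitor Cdkn1c, held by the imprinted list instead, was 59.5-fold higher at E12.5. Gas6 led this list too, followed by the thioredoxin inhibitor Txnip (7.57-fold), Cdkn1a (6.93-fold) and Gas1 (3.93-fold), while Cdkn1b was 2.26-fold higher in adult. Markers of hepatoblasts and erythroid cells, both dividing cells of the fetal liver, were also higher on the E12.5 array (medians 2.02 and 4.51, described further on). The latter was 2.24 over the 2 members detected on both arrays.

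Imprinted genes were higher at E12.5 in 16 of 19 detected members, with a median of 2.56 (percentile 100). Besides Dlk1, Asb4 and Cdkn1c, the growth factor Igf2 was among them, with signals of 12754 and 419 (30.4-fold). The exceptions were Sgce, 3.08-fold higher in adult, and 2 genes within 2-fold, of which Meg3, a maternally expressed RNA, had 9039 and 9285 with probe sets that differed in direction. The 7 detected oncofetal RNA-binding and chromatin genes (12 listed) were all at least 2-fold higher at E12.5 (median 3.40, percentile 100): the architectural protein Hmga2 by at least 95.7-fold, the mRNA-binding protein Igf2bp3 by at least 72.8-fold, Hmgb3 by 36.3-fold and Hmgb2 by 10.5-fold. Of the 7, 5 were detected at E12.5 alone and 2 on both arrays, so that this count also follows in part from the detection filter. Dlk1, Igf2 and Afp are also abundant in hepatoblasts, whose markers were also higher at E12.5.

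Transcription factors of the septum transversum and mesenchyme, the embryonic tissue next to the liver bud, were higher at E12.5 in 16 of 26 members and higher in adult in 1, with a median of 1.29 (percentile 99.9). The LIM homeobox gene Lhx2 was at least 40.9-fold, the T-box gene Tbx3 at least 21.2-fold and Msx2 at least 15.4-fold higher at E12.5, and Gata4 (8.96-fold) and Hand2 (8.75-fold) were detected on both arrays. The exception was Osr1, with signals of 63.7 and 1998, 31.3-fold higher in adult.

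Extracellular matrix genes divided, with 12 of 34 higher at E12.5, 8 higher in adult and 14 neither (median 0.53, percentile 74.1). At E12.5 the laminin chain Lama1 (at least 22.0-fold), periostin (Postn, at least 66.6-fold), Fbn2 and lumican (Lum, 23.3-fold) stood out, and Col1a1 had 4503 and 501. In adult the small proteoglycans Ogn (17.4-fold), Dcn (12.6-fold) and Bgn (12.3-fold) were higher. Secreted growth factors divided as well, with 13 of 43 higher at E12.5 and 12 in adult. Their median of 0.09 (percentile 10.0) turned to -0.29 with detected genes centred and -0.08 after quantile normalization. Dlk1, Ptn, Mdk and Igf2 led at E12.5, and Fgf1 (32.3 and 4630) and Bmp4 (11.4-fold) in adult, where Il6 was higher by at least 5.35-fold at a low signal of 24.4. Of 11 retinoid metabolism genes 5 were higher at E12.5 and 3 in adult, with a median of 0.20 (mean 1.09, percentile 34.4) that turned to -0.17 with detected genes centred and -0.11 after quantile normalization. It rose to 1.02 with probe sets averaged (percentile 95.4) and to 1.34 with the array median as the detection limit (percentile 98.9). The retinoic acid binding proteins Crabp1 (at least 44.6-fold) and Crabp2 (at least 14.2-fold) and the retinol carrier Rbp4 (13.5-fold) were higher at E12.5, and the retinal dehydrogenase Aldh1a1 in adult (10.9-fold). Rbp4 also serves as a hepatoblast marker in the closing part, and hepatoblast markers were higher at E12.5 as well.

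Complement and innate defence genes were higher in adult in 13 of 18 detected members and at E12.5 in 1, Cfi (7.55-fold), with a median of -3.06 (percentile 0). After C1ra, C1s1 and Slpi came C2, with signals of 132 and 12891 and no present call at E12.5. Antigen presentation and interferon-response genes were at least 2-fold higher in adult in all 24 detected members (median -4.20, percentile 0), among them the peptide transporter subunit Tap2 (at least 141-fold), Oasl2 (76.4-fold), Ifit1 (at least 71.1-fold) and Ifit3 (at least 39.4-fold). The class I genes H2-K1 (626 and 12447) and B2m (628 and 7548) belonged to the same list. Macrophage markers, from cells that also make complement and present antigen, were higher on the adult array as well, with a list median of -4.15 (-2.06 over members detected on both arrays).

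Immediate early and dissociation-stress genes, which collagenase digestion and sorting can switch on, were detected on both arrays in all 24 members. In adult 13 were at least 2-fold higher and at E12.5 only Dnajb1 (3.37-fold), with a median of -1.02 (percentile 0). The largest differences were those of Klf2 (7.63-fold), the small heat shock protein Hspb1 (5.03-fold), Socs3 (3.52-fold) and Klf4 (3.44-fold), and the high signals of Fos (9704 and 16978) and Egr1 (13091 and 17382) lay within 2-fold.

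Glycolysis genes were higher at E12.5 in 8 of 12 members and higher in adult in 1, with a median of 1.88 (percentile 100). The glucose transporter Slc2a1 was 6.50-fold, Pgam1 6.23-fold, Pgk1 5.66-fold and lactate dehydrogenase Ldha 4.83-fold higher at E12.5, and the platelet-type phosphofructokinase Pfkp was 13.4-fold higher in adult. Oxidative phosphorylation genes were higher at E12.5 in 6 of 22 members and within 2-fold in 16 (median 0.68, percentile 89.1), led by Atp5o (2.95-fold), Cycs (2.74-fold), Ndufs1 (2.23-fold) and Ndufb8 (2.19-fold, with probe sets that differed in direction). Of 24 listed ribosomal protein genes 14 were detected, where probe sets with several symbols are not counted. Of these 14, 12 lay within 2-fold and 2, Rpl27 (2.52-fold) and Rps6 (2.03-fold), were higher at E12.5, followed by Rps19 (1.93-fold) and Rps9 (1.91-fold), with a median of 0.38 (percentile 58.6). The 3' to 5' signal ratio of the control probe sets for Gapdh, itself a glycolytic gene, was 2.07 at E12.5 and 6.81 in adult, and for beta-actin 1.93 and 3.47.

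**Figure D2:**
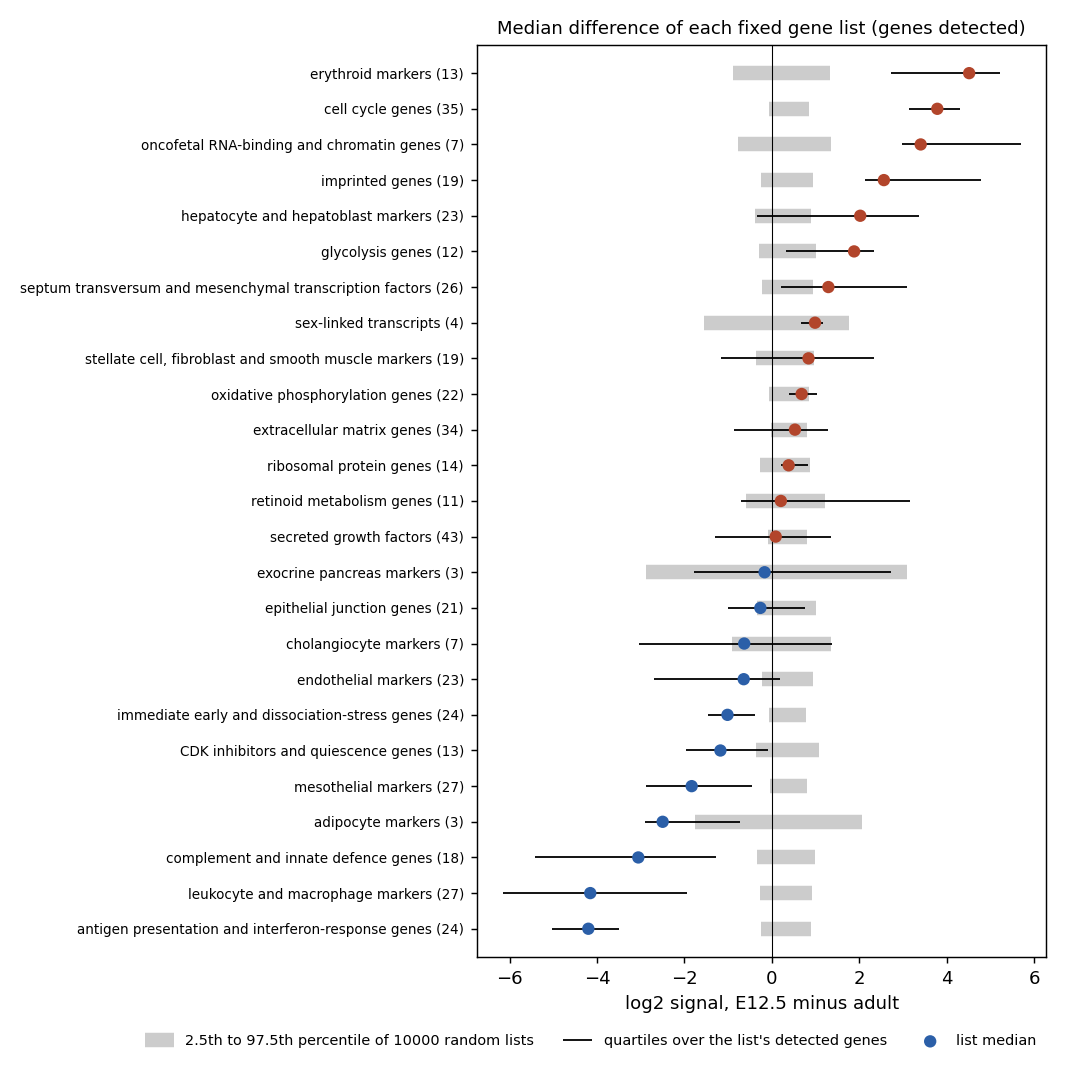
Median log2 difference (horizontal, E12.5 minus adult) of each of the 25 gene lists, with the number of detected genes in brackets; dots are medians, red above 0 and blue below, black lines the quartiles over the list's detected genes and grey bars the central 95% of 10000 random lists matched on signal. Cell cycle genes lie at 3.78 and antigen presentation genes at -4.20, while secreted growth factors at 0.09 (-0.29 with detected genes centred, -0.08 after quantile normalization), retinoid genes at 0.20 (-0.17 and -0.11), epithelial junction genes at -0.27 and exocrine pancreas markers at -0.17 (0.29 and 0.39 without scaling) are those whose sign depends on the scaling.

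Markers of other cell types of the liver differed between the arrays. Erythroid markers were higher at E12.5 in all 13 detected members (20 listed; median 4.51, percentile 100), with the embryonic globins Hbb-y (at least 55.2-fold) and Hbb-bh1 (at least 29.7-fold), the Rh-associated glycoprotein Rhag (at least 23.9-fold) and Gata1 (571 and 15.4, with a marginal call in adult). Of the 13, 10 were detected at E12.5 alone and 2 on both arrays, so that the count follows in part from the detection filter. The median was 2.24 over those 2, 2.73 with the floor, 3.20 with the pseudocount and 3.47 over 16 members with no filter. The 4 adult-type globin probe sets that match several genes, and are not in the count, were detected on both arrays, at 8118 and 2614 for beta globin and at 9252 and 5845 for the brightest of alpha globin, while 3 of the 4 that match 1 gene were absent on both. Hepatocyte and hepatoblast markers were higher at E12.5 in 13 of 23 members and higher in adult in 4, with a median of 2.02 (percentile 100). Fgb (at least 30.7-fold), Apob (16.9-fold) and Fgg (15.1-fold) followed Afp, and albumin (Alb, 7365 and 1584) and transthyretin (Ttr, 7063 and 697) were strong on both arrays. The members higher in adult were enzymes of mature hepatocytes at low signals, the largest being Cyp3a11 (at least 6.28-fold, at 85.6).

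Leukocyte and macrophage markers were higher in adult in 23 of 27 members and higher at E12.5 in 3 (median -4.15, percentile 0). The median was -2.06 over the 14 members detected on both arrays and -2.61 with no detection filter. Clec4f, Vsig4 (at least 284-fold) and the class II gene H2-Ab1 (at least 186-fold) were among those higher in adult, with Csf1r at 326 and 8606 and Cd5l at 48.4 and 4835. The scavenger receptor Cd163 had the largest ratio, but over an absent signal of 0.45 at E12.5, and its bound was 81.8-fold. The members higher at E12.5 were the granulocyte genes Mpo (at least 26.8-fold), S100a8 (7.74-fold) and S100a9 (6.81-fold). Endothelial markers were higher in adult in 10 of 23 members, with a median of -0.65 (percentile 0.09). Clec4g, a lectin of sinusoidal endothelium, was 73.6-fold, Ptprb 18.2-fold, the VEGF receptor Kdr 9.65-fold, Esam 8.93-fold and the hyaluronan receptor Stab2 6.99-fold higher in adult, whereas Ramp2 was 2.84-fold higher at E12.5.

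Stellate cell, fibroblast and smooth muscle markers went both ways, with 9 of 19 higher at E12.5 and 5 in adult (median 0.84, mean 0.14, percentile 94.3). Cygb (at least 49.3-fold), Clec3b (at least 31.5-fold) and Thy1 (21.4-fold) were higher in adult and Notch3 (at least 19.4-fold) and Pdgfra (6.81-fold) at E12.5, with Acta2 within 2-fold (2184 and 3811). Of 7 cholangiocyte markers 2 were higher at E12.5, Prom1 (17.8-fold) and Sox9 (at least 5.16-fold), and 3 in adult, the water channel Aqp1 (31.0-fold), the chloride channel Cftr (19.1-fold) and Krt19 (3.57-fold), with a median of -0.64 (percentile 6.02). The 3 detected adipocyte markers had a median of -2.50 (percentile 0.88), with Fabp4 (9.98-fold) and Cd36 (5.65-fold) higher in adult and Lpl (2.06-fold) at E12.5. The 3 detected exocrine pancreas genes had a median of -0.17 (mean 0.68, percentile 35.8), which turned to 0.39 without scaling: Cela1 was 10.6-fold higher in adult, Pnliprp1 at least 10.1-fold higher at E12.5 and Cel low on both (21.2 and 23.8). Of the sex-linked transcripts, the X-inactivation RNA Xist had signals of 2878 and 3456, with probe sets that differed in direction, and the Y-linked genes Kdm5d (120 and 37.1), Uty (39.4 and 19.8) and Eif2s3y (192 and 97.4) were detected on both arrays (median 0.98, percentile 85.7).

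**Figure D3:**
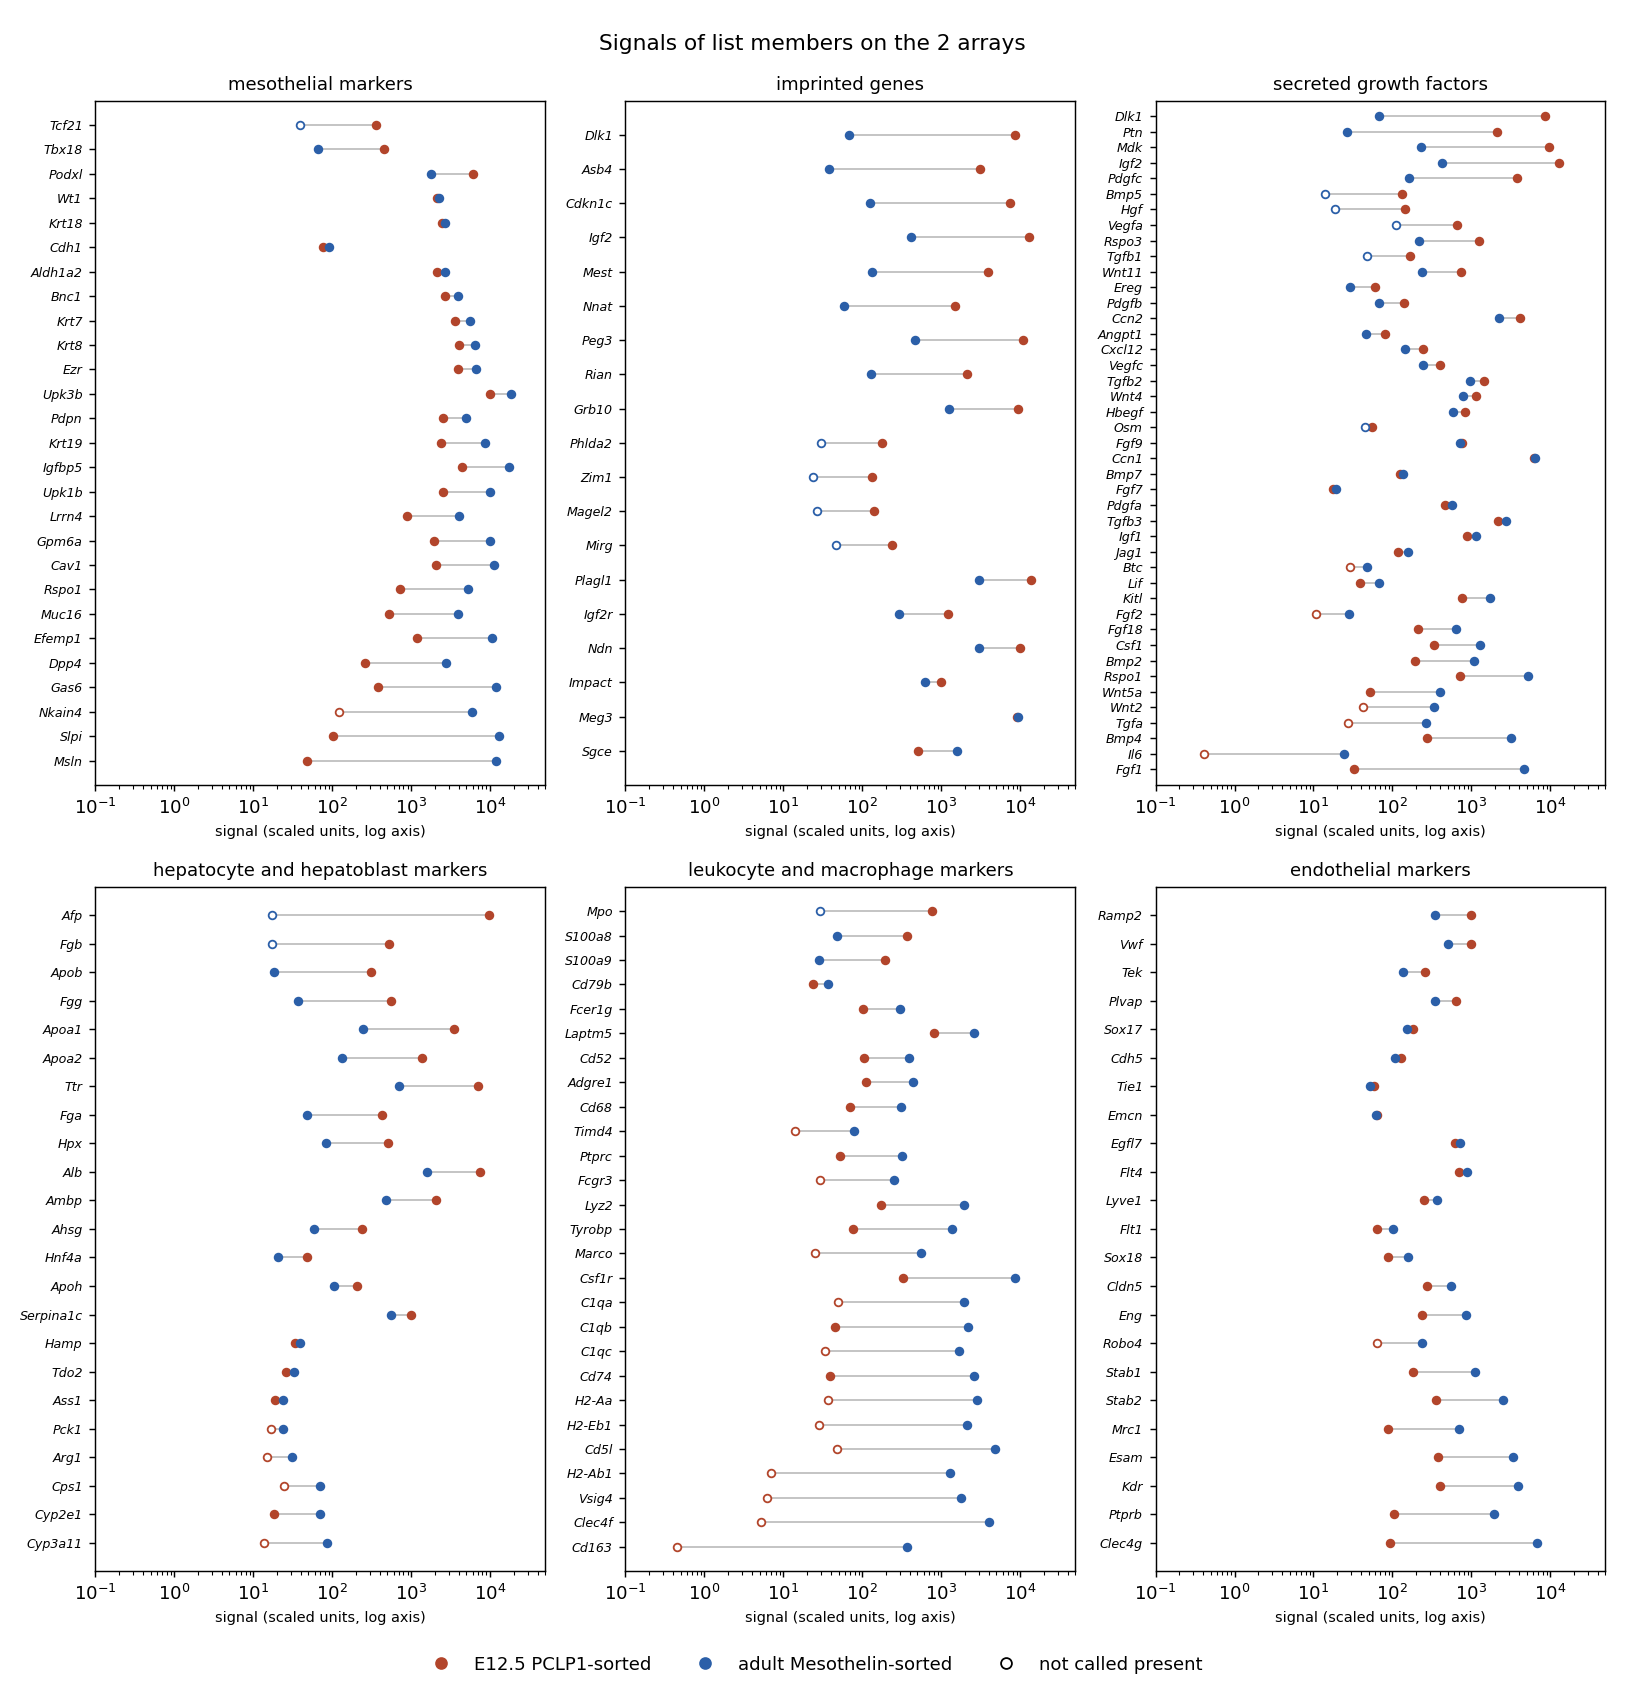
Signals of the detected members of 6 gene lists (horizontal, scaled units, log axis; 1 row per gene) at E12.5 (red) and in adult (blue), with open circles where the probe set was not called present and grey lines joining the values of a gene. Afp reached 9666 at E12.5 and Clec4f 4054 in adult, each without a present call on the other array, while Wt1 and Krt18 had nearly equal signals.

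The yardstick of 0.62 on the log2 scale covers differences between probe sets on these arrays and leaves out variation between animals, sorts and amplifications. The medians of the matched random lists lay between 0.18 and 0.43, so that a list percentile is read against that shift and not against 0.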

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

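The item in this part was looked at only after the data were examined, as a signal in control probe sets that the comparisons do not use. Probe sets for the lys, phe, thr and dap transcripts of Bacillus subtilis, which are commonly added to RNA as spiked controls before labelling, were mostly brighter on the adult array: over the 8 probe sets at the 3' ends the median raw signal was 2.42 times that at E12.5, with 8 of 8 higher, and 19 of the 24 probe sets for these transcripts were called present in adult and 7 at E12.5. The 3 control probe sets for a trp transcript, not counted here, were absent on both arrays and had lower raw signals in adult. The 18 probe sets for the bacterial and phage transcripts that are commonly added at hybridisation were detected on both arrays, with a median raw log2 difference of 0.22.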

How the results depend on the processing

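All alternatives reported here were fixed before the data were examined. Under other settings, the medians of growth factors, retinoid, epithelial junction and exocrine pancreas genes, which lay within the random range, changed sign. No list median that lay outside the central 95% of random lists changed direction under any of the 9 settings or when restricted to members detected on both arrays. That restriction left only 2 members each of the oncofetal and erythroid lists. No gene named by the fixed rule and at least 2-fold apart changed direction either, in the settings that held a value for it. C1s1, for example, had none without _x_at and _s_at probe sets. Several settings could not have reversed such genes. Centring and no scaling shifted differences by -0.38 and 0.56, and a floor or a pseudocount keeps the order of the 2 signals. Of the counts recomputed under alternatives, 34 stayed within 1.5 times the main count and 10 did not; of list medians, 260 moved by less than 0.62 on the log2 scale and 15 by more; of named genes, 1018 and 127.

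With the detected genes centred, 1658 genes were at least 2-fold and 458 at least 4-fold higher at E12.5, from the constant subtracted. Without scaling, 4770 and 814 genes were at least 2-fold and 1510 and 328 at least 4-fold higher at E12.5 and in adult. With no detection filter, 5045 and 3581 were at 2-fold and 1964 and 1772 at 4-fold, more genes being counted.

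Over members detected on both arrays, list medians were 4.03 for imprinted (15 genes), 4.29 for oncofetal (2 genes), -2.27 for complement (11 genes) and 2.24 for erythroid genes (2 genes). For leukocyte, cholangiocyte and exocrine pancreas genes they were -2.06 (14 genes), -1.84 (5 genes) and -3.40 (1 gene, so that it is no list value). With no detection filter they were 3.47 for erythroid, -2.61 for leukocyte and -0.28 for adipocyte markers. For erythroid markers the floor gave 2.73 and the pseudocount 3.20, both of which compress low signals. Oncofetal genes stood at 4.44 without _x_at and _s_at probe sets. Retinoid genes stood at 1.02 with probe sets averaged and 1.34 with the array median as the detection limit; the cause was not tested. The retinoid percentile ranged from 28.7 to 98.9 and that of stellate markers from 92.7 to 98.4, both highest with that limit, and that of adipocyte markers from 0.88 to 24.7, highest with no filter. It ranged from 3.79 to 49.2 for epithelial junction genes, highest with no filter, and from 4.19 to 45.8 for growth factors, highest with probe sets averaged.

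No paired analysis was possible because each group has 1 array and no result comes from a test.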

Other observations

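The families in this part were picked after the data were examined, by looking through 24 patterns of gene symbols, of which 12 were kept and 5 of these narrowed, so that how one-sided they are is no measure of chance. Of the tests further on, those of the scaling, of 5' loss, of neutrophils and of lymphocytes were chosen only after the result was seen. The other tests had limits set before their shares were computed. Their second marker lists, however, were written after the data were examined, so that they are no blind predictions. Interferon-inducible GTPases, which act in cell-autonomous defence, were at least 2-fold higher in adult in 10 of 10 detected genes (median log2 difference -4.13), led by Gbp6 (at least 156-fold), and in 9 of 10 under the wider pattern, which held Irgq and not Igtp. Annexins, calcium-dependent membrane-binding proteins, were higher in adult in 8 of 10 genes (median -2.47), among them Anxa1 (463 and 9018, 19.5-fold), with Anxa6 higher at E12.5 (2.17-fold, with probe sets that differed in direction). Of 8 S100a genes 6 were higher in adult, with S100a6 20.6-fold, and S100a8 and S100a9 at E12.5 (median -2.34). Of 15 chemokine genes 8 were higher in adult and none at E12.5 (median -1.25), with Cxcl2, a neutrophil attractant, at 177 and 5878. Macrophage markers (list median -4.15, and -2.06 over members detected on both arrays) and dissociation-stress genes (-1.02) were higher in adult beside these families, and the chemokines Ccl6 (at least 41.5-fold) and Ccl3 (at least 7.13-fold) are also made by macrophages. Cytochrome P450 genes were higher in adult in 17 of 31 and at E12.5 in 4, such as Cyp1b1 (7.97-fold; median -1.11), among those higher in adult Cyp4b1 (17.0 and 1771, with a marginal call at E12.5) and Cyp2s1 (8.78-fold). Timp2 was 12.6-fold and Timp3 2.29-fold higher in adult, with Timp1 within 2-fold (family median -1.20).

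In the other direction, 10 of 15 Hox genes were higher at E12.5 and none in adult (median 1.21; 11 of 17 and 1 with antisense transcripts), with Hoxb1 8.76-fold and Hoxc5 6.44-fold. Of 31 collagen genes 15 were higher at E12.5 and 5 in adult (median 0.98), the cartilage collagen genes Col9a2 (at least 52.9-fold) and Col11a1 (at least 32.3-fold) at E12.5 and the basement membrane gene Col4a4 in adult (at least 24.7-fold). The DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b and the demethylating enzyme Tet1 were higher at E12.5 (8.95, 3.22, 5.49 and 4.62-fold), and Tet2 lay within 2-fold. Insulin-like growth factor binding protein genes parted, with Igfbp1 (at least 120.0-fold) and Igfbp2 (9.09-fold) higher at E12.5 and Igfbp5 (3.91-fold), Igfbp6 and Igfbp7 in adult. Eph receptor genes parted as well, Epha7 at least 51.3-fold and Epha3 29.0-fold higher at E12.5 and Ephb6 (12.0-fold, marginal at E12.5) and Ephb1 (10.3-fold) in adult, and their median of 0.23 turned to -0.15 with detected genes centred and -0.08 after quantile normalization. Of 11 Sox genes 5 were higher at E12.5, with Sox11 33.0-fold, and none in adult, and their median of 0.27 turned to -0.10 with detected genes centred. The medians of the other families named in this part kept their sign under each scaling.

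More genes were at least 2-fold higher at E12.5 than in adult. The share of 2-fold differences towards E12.5 came to 45.57% with the detected genes centred and to 53.4% after quantile normalization. But centring brings this share near 50 whatever the cause, and quantile normalization gives both arrays the same distribution of signals. Either can thus remove a true difference too, so that a part of the authors' scaling cannot be told apart. Stronger loss of 5' sequence on the adult array was also tested. The 5' probe sets were lower in adult relative to the 3' ones by 1.717 for Gapdh and 0.8474 for beta-actin on the log2 scale, but positions of other genes' probe sets were not used here, so that its part stays open as well. A true difference in the number of genes that are higher at E12.5, between stages or sorts, stays open and untested.

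Macrophage and sinusoidal endothelial transcripts were higher on the adult array. Of 6 detected neutrophil and myeloid progenitor genes 0% were at least 2-fold higher in adult. Of 3 detected lymphocyte genes (14 listed) 33.33% were, and Cd8a was present at E12.5 alone, with probe sets that differed in direction. But 4 of these 9 genes (Cd79b, Mpo, S100a8 and S100a9) had been seen in the fixed lists. Fetal liver also makes myeloid cells itself, so that these shares cannot decide. On the adult array Mpo, Ngp, Prtn3 and Camp were called absent, and S100a8 and S100a9 had low signals (47.8 and 28.3). The lymphocyte genes Cd79b and Gzma were low there as well (37.0 and 44.9). Little RNA of these genes was thus seen on this 1 adult array, and a small part of either cell type cannot be told apart. Carry-over of resident macrophages may contribute: 86.67% of 15 detected genes of a second list were higher in adult, such as Ctss (118 and 2447) and Slc40a1 (241 and 2174), above the limit of 75%. For sinusoidal endothelial cells 75% of 12 were, such as Ehd3 (561 and 2296), exactly at the limit, where 3 of the 12 (Bmp2, Rspo3 and Tek) were also in the fixed lists. Sorting for Mesothelin would remove both cell types if complete, and expression of these genes by adult mesothelial cells themselves stays open and untested.

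Hepatoblast and erythroid transcripts were higher on the E12.5 array. Of 17 detected genes of a second hepatoblast list, of which Rbp4 was also in a fixed list, 70.59% were at least 2-fold higher at E12.5, such as Plg (937 and 82.7), and of 15 genes of a second erythroid list 53.33% were, such as Ermap (at least 20.1-fold). Both values lie between the limits of 50% and 75% chosen before these shares were computed, so that carry-over of either cell type, or of its free RNA, may contribute but cannot be told apart from expression by the sorted cells. Podxl is also carried by some blood-forming and endothelial cells, and sorting for its product would not remove those. Alb, Ttr and globins were detected on both arrays, globins in adult at 2614 (beta) and 5845 (the brightest of alpha). RNA read by these probe sets was thus present in the adult sample as well, and its source was not tested.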
